A study of Cristatella mucedo with 12 samples.

How the data were processed

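Polyadenylated RNA was sequenced from zones of mature Cristatella mucedo colonies and from statoblasts at stages of differentiation. Per the labels' protocols, libraries were made with a directional kit and run either paired-end on a HiSeq or single-end on a NextSeq instrument. The labels do not say which library was run in which way. HISAT2 2.1.0 and featureCounts 1.5.1 are named in the submitters' processing notes. The assembly, the annotation and the strand setting are not given in the sources used here. The authors deposited 1 table of expected counts per gene model, not normalized, with 1 column per library. That values can be fractions was seen in the values themselves. Contig, begin and end of each model were used as deposited. No reference genome was used, so exons and untranslated regions are not resolved. Of the 35949 models, 7781 overlap another and cannot be told from their partner with certainty.

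Libraries were grouped by title: central zone (replicates 1 and 2), edge zone (2 and 3), end part (1 and 3), middle part (2 and 3), and 4 statoblast stages of 1 library. Per the labels' protocols, 2 biological replicates were made of each sample, yet each statoblast stage has 1 library here. Whether its replicates were pooled, or another library is not analysed here, is not stated. The labels do not say whether replicates came from separate colonies, so p-values measure only the spread between these libraries. Totals were 14787598 to 26089274 counts in mature and 4738221 to 7805888 in statoblast libraries. Libraries of one group were not duplicates (chi-square per model 42.4 to 73.2). No library was left out, and 6144 models had no count in any. CPM values refer to library totals. A floor of 3 counts corresponds to 0.115 to 0.203 CPM in mature and 0.384 to 0.633 CPM in statoblast libraries.

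Expected counts were rounded to whole numbers, which moved no total by more than 0.00408%. They were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, glmQLFit, glmQLFTest, Benjamini-Hochberg, threshold 0.05). Each SE is the absolute log2 fold change or slope divided by the square root of the F statistic. It is not a standard error that edgeR itself gives. A fit of 4 group means over the 8 mature libraries gave the edge, end and difference tests. A fit of 2 groups over 12 libraries gave statoblast against mature, with stages and zones in the spread. A fit over the 4 statoblast libraries gave the slope per day, with the freezer library coded as day 0. Its filter uses no groups, so a model needs counts in all 4 stages. DESeq2 1.42.0 and limma 3.58.1 (camera, fry) were used for alternatives and set tests. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for library values and exact permutation tests, and matplotlib 3.10.9 for figures. The edgeR comparisons, most of the other settings tried, the gene lists and the rule for named genes were fixed before the data were examined. The exact permutation tests on library values were not part of that plan.

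The 18 fixed gene lists matched 0 identifiers, because the table gives names only for 16 mitochondrial models. They covered cilia, muscle, neurons, digestion, cell cycle, germline, ribosomes, ribosome biogenesis, oxidative phosphorylation, heat shock, dormancy, extracellular matrix, chitin and mucus, homeobox genes, signalling, immunity, mobile elements and plastids. None of the lists could be tested, including those that stood for other cell types and food. Chosen after the data were seen were the mitochondrial genes and 9 sets of models tested with camera. The sets were mitochondrial protein genes, contigs with a coverage of at least 160 or at most 40, overlapping models, models of at least 20000 or under 1000 bases, models higher in the end part, and models rising or falling over the statoblast days. Named identifiers are the 2 largest rises and the 2 largest falls per comparison among calls with a mean log2 CPM of at least 1 and groups that do not overlap. For the trend the course had to be monotone, and for the difference between dissections the overlap rule was not applied. The regions and single mitochondrial values were chosen after their values were seen.

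Runs were 3 or more neighbouring loci called with at least a 4-fold change in one direction, overlapping models counting as 1 locus, with positions shuffled 1000 times. For stages, all libraries were thinned to 4738054 counts, and a model was on at 10 or more counts. The rule of size took models with at least 50 counts in the highest library and a prior count of 2. Near-absent models had a mean under 0.5 CPM in one group and at least 5 CPM in the other. The limits for runs, near-absent models and models that are on were set after the data were seen.

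The tests were run on simulated data with 200 models changed. For edge against central zone, 19% of 2-fold and 93% of 4-fold changes were recovered (17591 models, 9.7% of calls false). For end against middle part these were 23% and 94% (17669 models, 7.1% false). For the difference between dissections they were 3% and 68% (17647 models, 9% false). For statoblast against mature they were 18% and 87% (17334 models, 4.5% false), and for the trend 9.2% and 83.7% (9742 models, 17.3% false). The simulated changes were few and balanced between rises and falls. In the data, far more models were called for edge against central zone and for statoblast against mature, and their medians moved with scaling. The simulated shares need not hold there. Alternatives covered normalization, test, filter, replicate number, libraries fitted, overlapping models and depth.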

Results

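Transcripts of the freshwater bryozoan Cristatella mucedo were counted in 12 bulk libraries of polyadenylated RNA. Bryozoans are colonial filter feeders, and statoblasts are the dormant capsules from which freshwater species found new colonies. Mature colonies gave 8 libraries in 4 groups of 2. The central and edge zones came from one kind of dissection, and the middle and end parts from elongated colonies. The other 4 libraries followed statoblasts from the freezer to day 2, day 4 and day 6, with 1 library per stage and therefore no replicate of any stage. Library totals ranged from 14787598 to 26089274 counts in mature colonies and from 4738221 to 7805888 counts in the statoblast series. The table listed 35949 gene models on 547 contigs. Only 16 mitochondrial models on contig 594 carried names; the files do not pair the other identifiers with names. Nuclear results are therefore given by contig position and by at most 2 identifiers in each direction. The name of the assembly is not given in the sources used here.

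The first comparison asked how the edge of a colony differed from its centre. The most extreme difference lay in gene models that were almost silent at the edge. A mean under 0.5 CPM (counts scaled to a common library total) at the edge and of at least 5 CPM in the centre was found for 73 models, and the opposite for 0. Their median was 13.3 CPM in central zone replicate 1, 63.9 CPM in central zone replicate 2, 32.9 CPM in the middle part and 17.2 CPM in the end part. Both edge libraries together held 401 counts over all 73 models. Many of the models with large losses were neighbours. On contig 32, 12 loci between bases 444147 and 648715 had medians of 60.2 and 668.7 CPM in the central libraries and 0.0195 and 0.0400 CPM in the edge libraries. On contig 152, 4 loci between bases 33917 and 72429 had medians of 103.7 and 730.7 CPM in the central libraries, against 0.0584 and 0 CPM at the edge.

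Of 18085 models tested, 2311 were higher and 1979 lower at the edge (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). At least 4-fold changes were fitted for 147 of the higher and 446 of the lower models. These formed 19 runs of 3 or more neighbouring loci with one direction, 17 lower and 2 higher at the edge. The runs held 80 loci, against a mean of 0.73 with shuffled positions (permutation p = 0.001, the smallest that 1000 shuffles can give). Here and in later comparisons, shuffling treats loci as independent, although neighbours that share reads need not be. On contig 37, 4 neighbouring loci between bases 2802731 and 2890972 were higher at the edge, with a median log2 fold change of 4.18. One of them was g29152 (bases 2848550 to 2855587), at 23.4 ± 3.32 CPM at the edge and 1.55 ± 1.10 CPM in the centre (SD, n = 2 each). Its log2 fold change was 4.30 (SE 0.50, edgeR adjusted p = 0.00011). On the same contig, g29216 (bases 3492378 to 3498380) had a log2 fold change of 3.62 (SE 0.31, edgeR adjusted p = 1.69e-05). The model g6572 on contig 6 (bases 6785737 to 6794872) had 318.0 ± 339.0 CPM (SD, n = 2) in the centre and 0 counts at the edge. Against a floor of 3 counts per library it was at least 2652-fold lower by the mean (edgeR adjusted p = 4.48e-05) and 652.6-fold by central zone replicate 1, the lower of both. On contig 32, g3078 (bases 456590 to 457181) had 310.3 ± 406.3 CPM (SD, n = 2) in the centre and 0 counts at the edge (edgeR adjusted p = 0.00037). It was at least 2588-fold lower by the mean, which rests on replicate 2, and 192.1-fold by replicate 1. All 4 had shared reads, and g6572 overlaps another model, so their levels are uncertain.

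None of the 14 mitochondrial protein genes passed the test in edgeR or in the DESeq2 Wald test, and 0 had an unadjusted p under 0.05 in either. Their log2 fold changes with TMM scaling ran from -0.52 to 0.27, with a median of 0.02. The direction depended on scaling, since all 14 had a lower mean CPM at the edge. They held 12.2% and 8.85% of counts in edge zone replicates 2 and 3, against 14.4% and 14.3% in the central libraries. Replicate 3 was low in the end and middle parts too, at 8.66% and 8.81%, and the central zone had no library of that number. The small mitochondrial ribosomal RNA MT_rrnS (contig 594, bases 65 to 869) stood at 2457.6 ± 72.4 CPM at the edge and 5917.9 ± 110.0 CPM in the centre (SD, n = 2 each). Its log2 fold change was -0.87 (SE 0.29, edgeR adjusted p = 0.0406), but its p adjusted over the 16 mitochondrial models alone was 0.137. The call held in 12 of 17 alternatives. It was lost without central zone replicate 1 or 2 (edgeR adjusted p = 0.0563 and 0.0822), without edge zone replicate 2 or 3 (0.205 and 0.159) and with a term for libraries numbered 3 (0.109). Over all 17 the log2 fold change ran from -1.27 to -0.68 and the adjusted p from 0.0018 to 0.205. Scaling by library totals alone gave 908 models higher and 3882 lower at the edge and moved the median of all models from -0.01 to -0.42. The count of calls was 842 without edge zone replicate 2 and 1554 without central zone replicate 1.

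**Figure D1:**
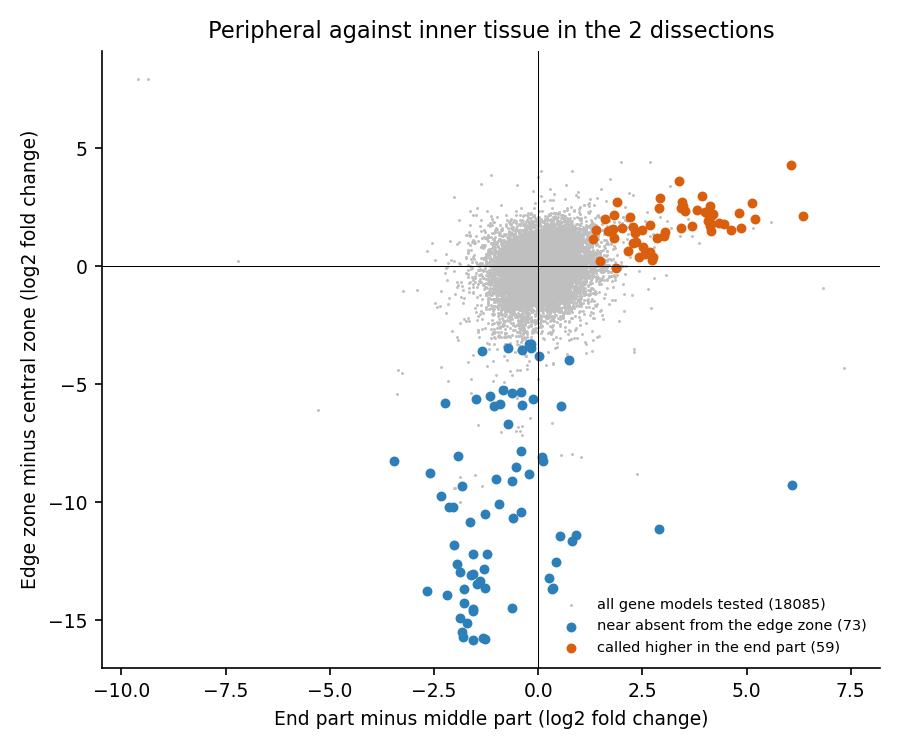
Log2 fold change of each of the 18085 gene models tested, end part minus middle part on the x axis and edge zone minus central zone on the y axis, from 2 libraries per group. Of the 59 models called higher in the end part (orange), 58 lie above 0 on the y axis; the 73 models near absent from the edge zone (blue) lie low on it, at fitted values that are no bounds where a group had 0 counts.

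The second comparison asked how the ends of elongated colonies differed from their middle. Few models passed, and most were higher at the ends. On contig 159, 6 neighbouring loci between bases 620806 and 719526 were higher, with a median log2 fold change of 3.81. The median of these loci was 46.4 and 47.5 CPM in the end libraries and 4.24 and 1.63 CPM in the middle libraries. It was the only run of 3 or more loci in this comparison (permutation p = 0.001, the smallest that 1000 shuffles can give).

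Of the 18085 models, 59 were higher and 3 lower in the end part (edgeR, adjusted p under 0.05), and 2341 had an unadjusted p under 0.05. Among those that met the rule for named models, the largest rise was that of g29152 on contig 37 (bases 2848550 to 2855587), which was also higher at the colony edge. It had 5.19 ± 2.56 CPM (SD, n = 2) at the ends and 3 counts in both middle libraries together. The ratio was 74.5, with a 95% counting interval of 25.5 to 361.0 (edgeR adjusted p = 0.00136). The model g10943 on contig 229 (bases 33268 to 35218), which overlaps another, had 2.83 ± 0.458 CPM (SD, n = 2) against 3 counts. Its ratio was 40.5, with a counting interval of 13.9 to 196.6 (edgeR adjusted p = 0.00211). Lower at the ends was g16271 on contig 2 (bases 9043825 to 9052080), at 1.93 ± 0.136 CPM against 8.62 ± 4.73 CPM in the middle (SD, n = 2 each). Its log2 fold change was -2.23 (SE 0.41, edgeR adjusted p = 0.0315). On contig 8, g5232 (bases 5535442 to 5538988) was lower too, at 52.3 ± 13.3 CPM against 201.7 ± 60.2 CPM (SD, n = 2 each; edgeR adjusted p = 0.02). Reads of all 4 were partly shared.

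None of the 16 mitochondrial models passed in edgeR or the DESeq2 Wald test, the lowest unadjusted p in edgeR being 0.149. The adjusted p of g16271 and g5232 ran up to 0.633 and 0.285 over the alternatives. The 62 calls became 300 with the DESeq2 Wald test, 681 without a filter on low counts and 1079 without end part replicate 3. They became 131 and 132 without central zone replicates 1 and 2, and 36 and 35 without middle part replicates 2 and 3.

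Models higher at the ends were mostly higher at the colony edge too, and the comparisons share no library. Of the 59 models, 58 had a positive log2 fold change at the edge and 49 were called higher there. Independent lists of these sizes would share 7.54 (Fisher's exact test across gene models, which are not independent, p = 1.79e-34). Fitting each dissection by its own 4 libraries gave 39 shared of 42. The median of the 59 was 2.20 and 1.58 CPM in the middle libraries, 11.5 and 12.2 CPM in the central, 15.9 and 15.4 CPM in the end and 28.4 and 30.5 CPM in the edge libraries. The edge zone was the highest of the 4 mature groups for 51 of them. The middle part was the lowest for all 59, which had been chosen on it.

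As a set the 59 were higher at the edge by camera (adjusted p = 1.81e-30), with adjusted p = 0.112 with an estimated correlation. In the statoblast series their median was 0 CPM in the freezer library and at day 2, 0.184 CPM at day 4 and 0.256 CPM at day 6. None of the 59 was called lower at the edge. The overlap depended on end part replicate 3: without it, 742 models were called higher at the ends, of which 132 were called higher at the edge, against 105.14 for independent lists, and 86 lower. Without a filter on low counts 474 were higher at the ends, with 162 higher at the edge, against 45.23, and 29 lower. Across all models the log2 fold changes of both comparisons correlated with Pearson's r = 0.186 and Spearman's rho = 0.105, and at a mean log2 CPM of at least 5 with 0.403 and 0.345 (3726 models), across gene models that are not independent.

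**Figure D2:**
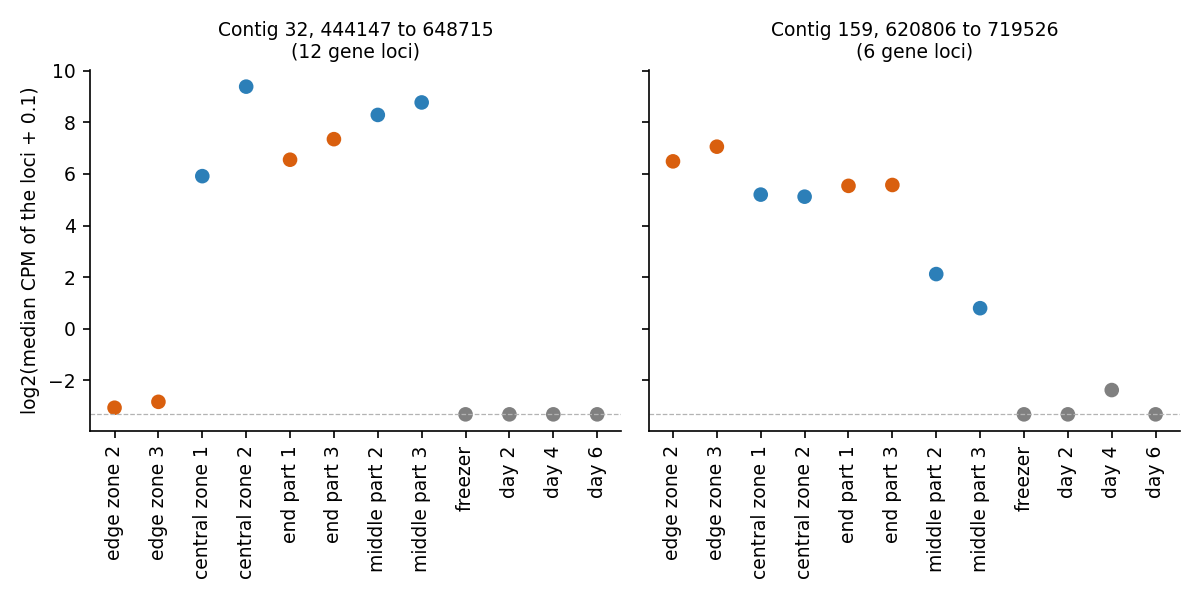
Median CPM per library over 12 loci of contig 32 (left) and 6 loci of contig 159 (right), as log2(CPM + 0.1); each point is 1 library, orange for edge and end, blue for central and middle and grey for statoblast stages, and the dashed line marks 0 CPM. The left region is near 0 in the edge and statoblast libraries and reaches 668.7 CPM in central zone replicate 2, and the right region is lowest among mature libraries in the middle part, at 4.24 and 1.63 CPM.

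The difference between the dissections was tested as the edge-to-centre change minus the end-to-middle change. The 12 loci of contig 32 that were near silent at the edge had medians of 93.7 and 162.9 CPM in the end and 312.5 and 437.1 CPM in the middle libraries, and were among those that passed. On contig 2, 4 loci between bases 8304340 and 8353615 also passed. Their medians were 473.6 and 262.6 CPM in the centre, 18.6 and 26.4 CPM at the edge, 255.8 and 273.9 CPM at the ends and 374.3 and 294.2 CPM in the middle. Of the 73 models near absent from the edge zone, 56 passed, but they had been chosen on the edge-to-centre change that enters this test.

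In all, 84 models had a higher and 310 a lower difference (edgeR, adjusted p under 0.05, 18085 tested). Those changed at least 4-fold formed 8 runs of neighbouring loci, all lower. None of the 16 mitochondrial models passed in edgeR or the DESeq2 Wald test, the lowest unadjusted p in edgeR being 0.216. Scaling by library totals alone gave 51 higher and 1362 lower. The 394 calls became 228 and 1233 without central zone replicates 1 and 2, 36 and 258 without edge zone replicates 2 and 3, 223 and 2944 without end part replicates 1 and 3, and 160 and 118 without middle part replicates 2 and 3.

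The next comparison set the statoblast series against mature colonies, and most of the transcriptome differed. Models called with at least a 4-fold change formed 717 runs of neighbouring loci, 636 lower and 81 higher in the statoblast series. The runs held 2992 loci, against a mean of 1412.64 with shuffled positions (permutation p = 0.001, the smallest that 1000 shuffles can give). The longest was lower, with 23 loci on contig 71 between bases 696083 and 981858. Their medians were 2.60 to 6.48 CPM in the mature libraries, 0 CPM in the first 3 stages and 0.256 CPM at day 6. Of the higher runs, those with the largest changes had a median over their loci near 0 CPM in every mature library, though not every locus was silent there. On contig 18, 6 loci between bases 3009584 and 3082926 summed to 4854 CPM in the freezer library, 9073 CPM at day 2, 10480 CPM at day 4 and 7934 CPM at day 6. They held 53 counts over all 8 mature libraries. On contig 68, 6 loci between bases 1900016 and 1955166 summed to 8310, 8136, 3907 and 3409 CPM in the same order, with 2525 counts over the mature libraries.

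Of 17896 models tested, 5139 were higher and 8622 lower in the statoblast series (edgeR, adjusted p under 0.05). The median log2 fold change of all models was -0.62, and library totals alone moved it to -0.09, with 6853 higher and 7218 lower. The groups did not overlap in CPM for 10890 of the calls; of all models tested 65% did not overlap, where chance gives 0.4%. The model g32717 on contig 18 (bases 2968330 to 2969515) stood at 1289 ± 320.2 CPM (SD, n = 4) with 0 counts in mature colonies. By the mean it was at least 6355-fold higher than 3 counts per library (edgeR adjusted p = 5.81e-08), and 4673-fold by its lowest library. On the same contig, g32738 (bases 3200742 to 3201587) stood at 993.6 ± 304.4 CPM (SD, n = 4) with 0 mature counts, at least 4898-fold higher by the mean and 2867-fold by the lowest library. The model g16635 on contig 138 (bases 132090 to 170880) had 3160 ± 1568 CPM (SD, n = 8) in mature colonies and 0 counts in every stage, at least 4991-fold lower by the mean and 1434-fold by the lowest library. On contig 10, g14202 (bases 5573213 to 5577249) had 1765 ± 1011 CPM (SD, n = 8) and 0 counts in every stage, at least 2787-fold lower by the mean and 589.8-fold by the lowest library. All 4 had shared reads.

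The library sets also differed in the counts themselves. Fractions other than 0.5 were found in 7.01% ± 0.595 (SD, n = 4) of models with a count in the statoblast libraries and in 30.8% ± 1.89 (SD, n = 8) in the mature libraries. The ranges did not overlap (exact permutation test, two-sided, p = 0.00404, the smallest it allows).

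Mitochondrial protein genes took a smaller share of counts in the statoblast series. The 14 genes held 5.35% ± 0.641 (SD, n = 4, over different stages) against 11.9% ± 2.69 (SD, n = 8) in mature colonies (exact permutation test, two-sided, p = 0.00404, the smallest it allows). All 14 were lower in edgeR, by log2 fold changes of -2.25 to -1.19, and the DESeq2 Wald test called all 14 as well. The change was -2.25 for MT_atp6, a subunit of ATP synthase (SE 0.30, edgeR adjusted p = 1.11e-05). It was -1.99 for MT_nad4, a subunit of the respiratory NADH dehydrogenase (SE 0.27, edgeR adjusted p = 1.31e-05), and -1.89 for MT_cox3, a subunit of cytochrome c oxidase (SE 0.35, edgeR adjusted p = 0.000182). Their median was -1.61, against -0.62 for the other models. The set did not stand apart by camera (adjusted p = 0.133, and adjusted p = 0.869 with an estimated correlation). With day 6 alone against mature colonies, MT_nad3_0 and MT_nad3_1 were no longer called, at -1.27 and -1.31.

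The mitochondrial ribosomal RNAs MT_rrnS and MT_rrnL were not called between the sets (edgeR adjusted p = 0.225 and 0.537), and the stages lay far apart. A fit of 8 group means, with the spread taken from mature colonies alone, called both lower, at -1.46 and -0.94 (edgeR adjusted p = 2.28e-06 and 0.000262). Without the day 6 library MT_rrnS was called too, at -1.38 (edgeR adjusted p = 0.036). Over all alternatives the adjusted p reached 0.695 for MT_rrnS and 0.951 for MT_rrnL. Their joint share was 0.127% in the freezer library (95% Wilson interval 0.124 to 0.130), 1.02% at day 2 (1.01 to 1.03), 0.922% at day 4 (0.914 to 0.930) and 1.82% at day 6 (1.81 to 1.83). Intervals and floors cover counting error only. MT_rrnS stood at 395.0, 3782.6, 3553.1 and 7572.9 CPM over the stages. MT_cox1 stood at 8669.8, 12894.3, 13251.0 and 12484.9 CPM.

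**Figure D3:**
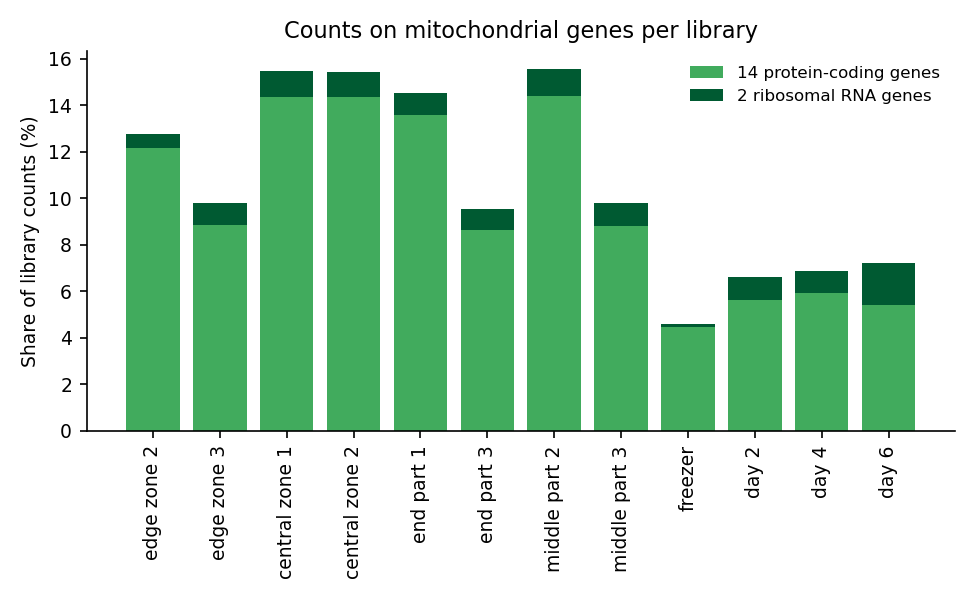
Share of each library's counts on mitochondrial genes in percent, stacked as 14 protein-coding and 2 ribosomal RNA genes, with 1 bar per library. Protein-gene shares are 4.44% to 5.93% in the statoblast stages and 8.66% to 14.4% in the mature libraries, and the ribosomal RNA part of the freezer bar is 0.127%.

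Within the statoblast series, more models went from 0 to at least 10 counts between the day 2 and day 4 libraries than at the other steps. At a common depth of 4738054 counts, 329 models did so at that step. The numbers were 72 from the freezer to day 2 and 21 from day 4 to day 6, and 8, 3 and 3 models went the other way over the consecutive steps. Between mature libraries of one group such switches numbered 2 to 8. Counting every model that first reached 10 counts, from any lower count, gave 665 at day 2, 980 at day 4 and 448 at day 6. Of the 329 models, 261 (79.3%) had at least 10 counts in every mature library. Among all 11440 models with at least 10 counts at day 4, 9068 did so, a like share. Of 11146 models at that level in all mature libraries, 73.4% reached it in the freezer library, 74.7% at day 2, 81.4% at day 4 and 82.7% at day 6. These steps compare single libraries and have no replicate check.

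A linear trend over the days was called for 587 rising and 412 falling models of 9887 tested (edgeR, adjusted p under 0.05). In simulated data 17.3% of the calls of this test were false, more than the threshold of 0.05 allows. Over the 6 days, 247 of these rose and 70 fell at least 4-fold. With 1 library per stage, the spread in this test is the departure from a straight line. It is not a spread between replicates of a stage. Among those that met the rule for named models, the steepest rise was that of g35472 on contig 17 (bases 205427 to 232327), at 2.68, 17.1, 320.5 and 493.2 CPM over the stages and 1229 to 1600 CPM in mature libraries. Its log2 slope was 1.34 per day (SE 0.17, edgeR adjusted p = 0.00642). The model g7912 on contig 51 (bases 1788688 to 1905385), which overlaps another, stood at 3.03, 3.17, 44.0 and 68.4 CPM (log2 slope 0.86 per day, SE 0.13, edgeR adjusted p = 0.00774). Under the same rule, the steepest fall was that of g14148 on contig 10 (bases 4663304 to 4664391), at 82.4, 24.7, 6.08 and 4.61 CPM, with 0 counts in all 8 mature libraries. Its log2 slope was -0.74 per day (SE 0.08, edgeR adjusted p = 0.00537). On contig 1, g17470 (bases 2172887 to 2180561) stood at 159.7, 31.2, 18.8 and 10.6 CPM (log2 slope -0.65 per day, SE 0.07, edgeR adjusted p = 0.00537). Of these 4, only g14148 had no shared reads. On contig 65, 3 neighbouring loci between bases 823241 and 838141 rose, with medians of 6.78, 69.7, 136.5 and 230.3 CPM. By a rule of size without a test, 166 models rose and 38 fell at least 4-fold without turning back.

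Of the mitochondrial genes, MT_rrnS was called in the trend (edgeR adjusted p = 0.0426, from 0.0135 to 0.148 over the alternatives) and lost its call without the freezer library, with thinned libraries and with the DESeq2 Wald test, 7 of 10 alternatives keeping it. Its log2 slope was 0.561 per day (SE 0.145). The edgeR p adjusted over the 16 mitochondrial models alone was 0.0454 for MT_rrnS and 0.0454 for MT_rrnL, which was not called over all models (adjusted p = 0.0523). None of the 14 protein genes was called in edgeR or the DESeq2 Wald test, the lowest unadjusted p in edgeR being 0.071. Without the freezer library 4 models were called in all, without day 4 463 and without day 6 525. Scaling by library totals alone gave 655 rising and 290 falling, and the test covered 0 of the 650 models that went from 0 counts in the freezer library to at least 10 at day 6.

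**Figure D4:**
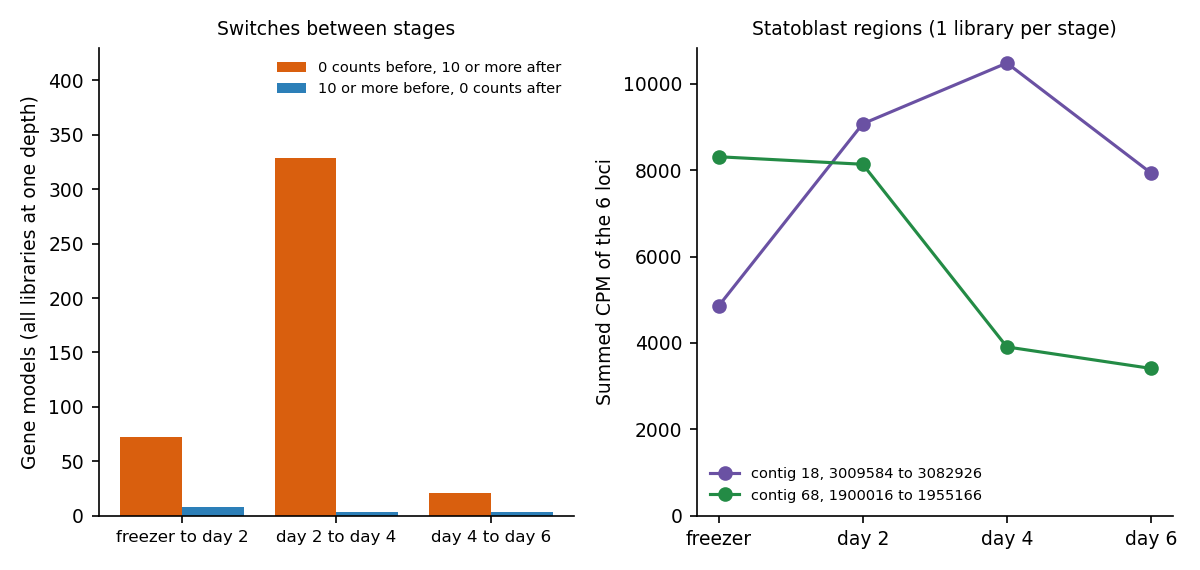
Left, numbers of gene models going from 0 to at least 10 counts (orange) or back (blue) between consecutive stages, with all libraries at one depth; right, summed CPM of 6 neighbouring loci on contig 18 (purple) and on contig 68 (green), with 1 library per stage. The step from day 2 to day 4 holds 329 switches on, and the sum on contig 68 goes from 8310 CPM in the freezer library to 3409 CPM at day 6.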

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

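Chosen only after the result was seen were the tests of a deviating central library, of finished statoblasts in the centre, of near-identical copies, of a sequencing or library batch, and both tests of the mitochondrial share.

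The change between zones differed between the dissections for 394 models by the test of the difference itself. Its named identifiers were g2404 on contig 109 (log2 difference 3.94) and g19190 on contig 5 (2.999), higher, and g25767 on contig 21 (-15.36) and g3078 on contig 32 (-14.53), lower. Calls held in 10 of 15 alternatives for g2404 (edgeR adjusted p up to 0.237), 9 for g19190 (up to 0.235), 8 for g25767 (up to 0.758) and 14 for g3078 (up to 0.112). The value of g3078 is a fitted value against 0 counts at the edge and no bound. The counts of g25767 were 3793 in central zone replicate 2, 505 in end part replicate 1 and at most 10 in the other mature libraries. End part replicate 1 lay apart from the other mature libraries in the share of models with fractions other than 0.5, at 26.6% against 29.6% to 32.2%. Among models with 50 to 200 counts it lay at 25.6% against 28.3% to 30.6%. Chance marks about 1 in 20 such groups, and 22 were tested.

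The 73 models near absent from the edge zone were higher in central zone replicate 2 than in replicate 1 in 69 cases. A single deviating central library was argued against, since replicate 1 alone gave 58 such models, and 1 in the opposite direction. For finished statoblasts like those sampled, lying in the centre, 45 of the 73 stayed under 0.5 CPM in all 4 statoblast libraries and 17 reached 5 CPM in any. All 73 had fractional counts in some library, however, and fractions were rarer in the statoblast libraries. How far that bears on their counts was not tested, so finished statoblasts in the centre cannot be excluded. Near-identical copies that share reads cannot be told apart from separate genes, because only 9 of the 73 had no fractions other than 0.5. Statoblasts still forming in the colony were not analysed here by themselves, and they and any other biological difference between the zones stay open, untested.

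The statoblast series and mature colonies differed in 13761 models. Depth was argued against as the whole cause, with 11080 calls after thinning. Among 322 models with whole counts in all 12 libraries 80.4% were called, so calls were also found without fractions. Whole counts are rarer in the mature libraries, so the choice of these models is tied to the comparison itself. It cannot decide on the division of shared reads in the other models, which stays open. Of 100 splits of the 12 libraries into 4 and 8, 1 gave as many calls, the real one (highest other 0). Every other split put statoblast and mature libraries into the same group, which widens the spread. Few calls were therefore fixed in advance for them, and they cannot decide on chance. A sequencing or library batch cannot be told apart from development, because fractions other than 0.5 separate exactly these libraries at 50 to 200 counts (7.02% against 28.7% of models, exact permutation p = 0.00404). Both stay open.

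Mitochondrial genes held 9.70% ± 0.142 of counts (SD, n = 3) in mature libraries numbered 3 and 14.8% ± 1.19 (SD, n = 5) in those numbered 1 or 2 (exact permutation test, two-sided, p = 0.0357, the smallest it allows). The grouping by number was not planned, so this p-value is only descriptive. It also ignores zone, and the central zone had no library numbered 3. The lowest correlation of deviations among libraries numbered 3 was -0.13, and the other pairs had 0.127 and 0.143. With 2 libraries per group, each deviation mirrors that of the group mate, numbered 1 or 2. These correlations therefore cannot decide on a batch acting on genes at large, which stays open. The log2 ratio of libraries numbered 3 to their group mates rose with gene length over the 14 protein genes (Spearman's rho = 0.582, permutation p = 0.032, across genes that are not independent), which is consistent with a loss of short transcripts as a hypothesis. Length alone did not order the genes, since the lowest ratio was that of MT_cox3 (777 bases, -1.04), while the shorter MT_cox2 (681 bases) and MT_nad4l (303 bases) stood at -0.41 and -0.54. A difference between colonies stays open and was not tested.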

How the results depend on the processing

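Settings chosen after the data were seen were merged overlapping models, thinning, the term for libraries numbered 3, whole-count models, the set tests and the near-absent rule.

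Edge against central zone (4290 calls) stayed within 1.5 times in 16 of 18 alternatives and ran from 842 to 5100 with a library left out. End against middle part (62) ran from 35 to 1079 with a library left out, with 300 by DESeq2's Wald test and 681 without a filter. The difference between dissections (394) ran from 36 to 2944, with 1504 by DESeq2's Wald test, 2217 without a filter, 1413 with library totals and 223 with the term for libraries numbered 3. Statoblast against mature (13761) ran from 13229 to 13852, with 259 among whole-count models, where 322 were tested. The trend (999) ran from 4 to 857 with a stage left out, and the slope per stage step is equivalent by construction. Apart from fewer models or libraries, the cause was not tested. A lone library was assumed to vary like the other groups. The limit of 1.5 times compares only how many models were called, not their direction. For edge against central zone, scaling by library totals left most calls lower at the edge, whereas in the reported fit slightly more were higher.

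Correlations of deviations between libraries of the same replicate number ran from -0.13 to 0.272. The highest was that of central zone and end part, the only pair numbered 1. Pairs numbered 2 and 3 had positive and negative values. With 2 libraries per group, each deviation mirrors that of the group mate, which bears another number. The correlations therefore cannot decide on a pairing by number, which stays open. The replicate block gave 4293 calls for edge against central zone, 103 for end against middle part and 342 for the difference.

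Of 312 values of named identifiers, 280 kept their side of the threshold, 32 lost it and 0 changed sign. MT_rrnL, not called in the reported fit, changed sign against mature colonies with library totals (0.21) and day 6 alone (0.51), and ran from -0.85 to 0.021 with a library left out. MT_rrnS, not called either, did so with day 6 alone (0.23). Both were called lower with 8 group means, and MT_rrnS also without day 6. The cause was not tested. Models higher in both dissections (49, against 7.54 for independent lists) ran from 26 to 162, and the 132 without end part replicate 3 stood against 105.14. The correlation between dissections was 0.403 (Pearson) and 0.345 (Spearman) at a mean log2 CPM of at least 5. By size, prior counts of 0.5 and 10 gave 177 and 133 rising and 42 and 34 falling models. The near-absent rule gave 64 models with TMM scaling and 58 to 82 with a library left out. Camera with an estimated correlation and fry were not run on the fixed lists, which matched 0 models. In simulated data at these depths and library numbers, with few and balanced changes, 3% to 23% of 2-fold changes were recovered.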

Other observations

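All tests in this part were chosen after the data were seen. Models that went from 0 to at least 10 counts during statoblast development were followed into the mature colonies, which share no library with the series. Of the 329 that did so between day 2 and day 4, 316 were tested between edge and central zone. At the edge 88 were higher, against 40.4 for independent lists (Fisher's exact test across gene models, which are not independent, p = 7.02e-13), and 27 lower, against 34.6 (Fisher's exact p = 0.202). Of the 650 that did so between the freezer and day 6, 606 were tested. At the edge 126 were higher, against 77.4 (Fisher's exact p = 1.96e-08), and 80 lower, against 66.3 (Fisher's exact p = 0.0738). At the ends of elongated colonies 3 of the 606 were called higher. The overlaps with the edge were not recounted with library totals alone, which left far fewer models called higher there. Nor were they set against models of like expression.

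Spearman's rho with the mature mean was 0.476 in the freezer library, 0.491 at day 2, 0.598 at day 4 and 0.613 at day 6, across 17896 models that are not independent. Between mature libraries it was 0.898 to 0.990. On contig 54, 3 loci between bases 34687 and 84539 had medians of 33.2 CPM in the freezer library and 3.33 CPM at day 6. On contig 4, 3 loci between bases 8012011 and 8068808 went from 5.71 to 36.6 CPM. By camera, models falling over the statoblast days were higher at the ends than in the middle as a set (361 models, median log2 fold change 0.31, adjusted p = 2.96e-08). The adjusted p was 0.397 with an estimated correlation and 0.189 by fry, and 2 of the models were called. Models rising over those days were lower at the ends by camera (586 models, median -0.15, adjusted p = 0.000769), with 1 called higher and 1 lower. For them the adjusted p was 0.397 with an estimated correlation and 0.189 by fry.

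Models on contigs of high coverage were lower at the ends by camera (68 models, adjusted p = 0.0475), but not with an estimated correlation (adjusted p = 0.547) or by fry (adjusted p = 0.532). Contigs of low coverage and overlapping, long and short models did not pass camera's test in any comparison, the lowest adjusted p being 0.0547.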
